A study of Sus scrofa with 24 samples.

How the data were processed

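Total RNA of 24 vein samples was extracted with the Qiagen RNeasy Micro kit and labelled with the Agilent Quick Amp kit for 2 colours, per the labels' protocols. The arrays were 16 Agilent pig arrays with 43603 different probes, scanned and quantified with Agilent Feature Extraction 10.5.1.1, per the file headers. Each sample's group, replicate number and dye came from the labels: the jugular control was Cy3 on the array that carried the anastomosis sample of the same number and day in Cy5, and the downstream sample was Cy5 on another array whose green channel had no sample in the labels (8 array files). The deposited scanner files gave intensity values on a linear scale, namely the mean foreground and median local background of each spot in each channel, with no normalisation, and also the intensity values that Feature Extraction had background-subtracted and dye-normalised, per the file headers. The arrays lay on 7 slides and came from 5 scans; those of replicates 1 and 2 were extracted with an earlier version of the protocol than those of replicates 3 and 4, per the file headers. Day 5 and day 14 shared a slide for replicate 4 and a scan for replicates 3 and 4. The authors also deposited a value table of log2 values for the same samples; how it was made is not given in the sources used here.

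From the scanner files, each channel was corrected with normexp (offset 50, fitted on all spots), normalised by loess within the array with control and outlier-marked spots at weight 0, and by the Aquantile method between arrays, in limma 3.58.1 with R 4.3.3. Each sample was then represented by the log2 value of its own channel, control spots and spots marked as outliers were left out, and spots of a probe were averaged. Of the probes, 9104 (20.9%) had a gene symbol, 256 only a numbered locus and 34243 no name, and 0 had several symbols. Symbols came from a numbered locus read as a gene ID (2097), a RefSeq accession (670), the gene name in the files (5743), an older annotation among the files (531) or a protein name in the description (63), through tables of gene IDs and RefSeq genes; for 4528 probes named by both annotation versions in the files, 98.7% had the same symbol. The 9104 probes covered 6155 symbols, and for several probes of a symbol the brightest was used. Features well above background in at least 4 of the 24 samples were tested, 33325 in all, of which 5812 had a symbol. The share of probes well above background (56.9% to 80.2%) stands in for depth and was lower in replicates 1 and 2.

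Differences between sites within a day, and the change of these differences between days, were estimated with lmFit and eBayes on all 24 samples, with a term per group and a block for each replicate number within a day (8 blocks of 3 samples, 12 residual degrees of freedom), so that all groups shared an estimate of the spread. Day 14 was compared with day 5 in the 8 samples of a site with no block. Two-sided p-values were adjusted by Benjamini-Hochberg over all features of a comparison, with 0.05 as the threshold. There were 12 comparisons, and the number past 2-fold is given beside each count. Chance alone puts a 0.05 share of features at an unadjusted p under 0.05. Whether the 3 sites of a number and day come from 1 animal is not stated in the labels. The block came from the array design, in which control and anastomosis sample share an array, and the pairing was checked on the deviations from the group means. Samples of the same number and day correlated at 0.22 to 0.82 in the 8 pairs on an array. In the 16 pairs on different arrays it was 0.19 to 0.76, and all pairs lay over 0.1. Samples of the same site and number on different days also correlated, at 0.073 to 0.622 (11 of 12 over 0.1). Each block lay on 1 slide, so these correlations cannot show that a block is 1 animal.

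The 25 gene lists were of cell cycle, contractile smooth muscle, fibrillar collagen and matrix, collagen processing and crosslinking, matrix proteases and inhibitors, endothelial markers, flow-responsive endothelial genes, monocyte and macrophage, neutrophil, T and NK cell and B and plasma cell markers, inflammatory cytokines and chemokines, interferon response, complement and coagulation, hypoxia and glycolysis, mitochondrial energy metabolism, growth factors and receptors, TGF-beta and BMP signalling, Wnt signalling, endoplasmic reticulum folding, adipocyte, skeletal muscle, Schwann cell and nerve, blood cell, and lymph node markers. They were tested with camera in limma (preset correlation 0.01, at least 5 measured members) and adjusted over the 25 lists of a comparison, again with an estimated correlation, and with fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. A list's median is that of its members' fitted differences. The sample groups, comparisons, tests, lists, naming rule and all alternatives except 3 were chosen before the data were examined. Named were the 8 largest rises and 8 largest falls among symbol genes past the threshold that moved alike in 4 of 4 pairs; where under 3 passed, the 5 smallest p, said to miss; the 3 members of each list with the smallest p; and fixed genes, namely 7 housekeeping genes with MYH11, ACTA2, COL1A1, PECAM1, PTPRC and MKI67. TBP and GAPDH were not among the symbols tested. The levels of ADIPOQ, FABP4 and LPL in single samples were chosen after their values were seen. Where no sample of a group was well above background, a bound was formed from the mean of the bright group and, per array of the dim group, the higher of the lowest signal well above background and the probe's own signal.

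The value table was set against the scanner values. In replicates 1 to 3, its 18 columns correlated with the log2 signal of the sample's own channel at 0.989 to 0.994, so that it holds levels, not ratios; the log2 scale and the centring were inferred from the values, and any step per probe stays unknown. The 6 columns of replicate 4 correlated at 0.962 to 0.972, and 4 of 4 differences formed from them lay nearer the scanner values of replicate 3 than of replicate 4. The column medians for replicates 1 to 4 were 7.35, 7.34, 7.40 and 7.40 in the jugular control, 7.35, 7.35, 7.40 and 7.39 at the anastomosis and 7.38, 7.37, 7.42 and 7.39 downstream at day 5, and 7.37, 7.38, 7.40 and 7.40, 7.38, 7.38, 7.39 and 7.40 and 7.39, 7.37, 7.41 and 7.39 at day 14. It was used only as an alternative.

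Alternatives were processed signals or no background correction in place of normexp; loess with no between-array step, quantile normalisation of single channels, or median centring in place of loess; within-array log ratios; no filter or a stricter filter (12 samples) on dim probes; the mean of a gene's probes; no replicate block, a replicate block between days, or the slide as a block; only the samples compared; sample weights; eBayes with trend and robust; each replicate left out; the value table; an estimated correlation and fry. Where a list kept its call without a replicate but its median moved by over 1.5 times, that median follows the one from all samples, to which the adjusted p belongs. Added after seeing the data were the value table without its replicate 4 columns, replicates 1 and 2 only and replicates 3 and 4 only. Comparisons that share the control were set against 20 draws of unchanged groups that shared simulated controls, and against controls split into sets of 2.

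The fit was tested on 33275 simulated, uncorrelated genes. For the anastomosis against the control at day 5, 77 and 91 of 100 genes with log2 changes of 1 and 2 were recovered. False calls numbered 13. For day 14 against day 5 at the anastomosis these were 19 and 75, with 1 false call. A shifted cell cycle list was called for the first comparison (adjusted p = 1.59e-34, 2.03e-07 with an estimated correlation) with 0 of 24 other lists. This tests no list of correlated genes. Other software was data.table (version 1.17.8), statmod 1.5.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The unlabelled green channels entered only the normalisation within and between arrays, and through it the values of the red channels, the log ratio alternative and a check of what they resemble.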

Results

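Gene expression was measured in veins of pigs that carried an arteriovenous haemodialysis graft, a conduit between an artery and a vein. The venous end of such grafts narrows when cells and matrix build up on the inner wall (neointimal hyperplasia). The samples were total RNA from 3 vein sites: the external jugular vein as the control, the venous anastomosis where graft and vein were joined, and the vein segment downstream of the anastomosis. Each site was sampled at day 5 and day 14 after graft placement with 4 replicates, which gave 24 samples in 6 groups of 4. The labels call the replicates biological, so the p-values measure the spread between such replicates. Whether day 5 and day 14 of one number, or the 3 sites of one number and day, are the same animal is not stated. The samples were hybridised to 16 Agilent pig arrays of 2 colours. Every jugular control was in Cy3 and every anastomosis and downstream sample in Cy5, so that dye and site were confounded in a comparison with the control on a given day. A dye shift that is constant over the days cancels in the change of such a difference between days. Per sample, 56.9% to 80.2% of the probes were well above background, with a median spot signal of 48.5 to 230.2. The precision is limited by 4 samples per group. The samples of replicates 1 and 2 were dimmer (56.9% to 73.9% well above background) than those of replicates 3 and 4 (70.1% to 80.2%). The first principal component, with 26.7% of the variance, separated these pairs of replicates. In all, 33325 features were tested, of which 5812 had a gene symbol. Fold changes are on the log2 scale with ± SE from limma and n = 4 per group, and levels are normalised log2 intensities with ± SD. Genes named first in a comparison with the control moved the same way in 4 of 4 pairs.

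The comparison of the anastomosis with the jugular control at day 5 asked how expression at the graft junction differed from that of the control vein early after graft placement. IBSP (bone sialoprotein) rose by 5.08 ± 1.07, SPP1 (osteopontin) by 4.53 ± 1.06, SAA3 (an acute-phase serum amyloid) by 4.45 ± 1.14 and the chemokine CXCL14 by 3.93 ± 0.77 (adjusted p from 0.00330 to 0.0144). IBSP was well above background in 2 of 4 control samples. CCNB1, the cyclin that drives entry into mitosis, stood at 12.20 ± 0.12 at the anastomosis and 8.57 ± 0.10 in the control, a 12.4-fold difference (3.63 ± 0.56, adjusted p = 9.88e-04). The spindle gene DLGAP5 rose by 3.38 ± 0.49 and the cell cycle transcription factor MYBL2 by 3.36 ± 0.53. TMEM158, a membrane protein induced by Ras signalling, rose by 3.38 ± 0.31 (adjusted p = 1.45e-04). The largest fall was in the ferritin receptor SCARA5 (-5.84 ± 0.51, adjusted p = 1.18e-04). The neurotrophin receptor NTRK2 (-4.71 ± 0.61), myocilin (MYOC, -4.64 ± 0.86), the cytoskeletal linker periplakin (PPL, -4.46 ± 0.46) and the pyruvate dehydrogenase kinase PDK4 (-4.43 ± 0.62) fell with it. So did the potassium channel subunit KCNAB1 (-4.23 ± 0.86), FAM107A (-4.04 ± 0.69) and the matricellular gene SPARCL1 (-3.89 ± 0.67), with adjusted p from 1.18e-04 to 0.00420 over these 8 genes.

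Cell cycle genes rose in 25 and fell in 0 of 27 cases, with a median difference of 1.93 (adjusted p = 2.79e-19, and adjusted p = 0.503 with an estimated correlation). Examples were CDK1 (3.30 ± 0.49), TOP2A (2.95 ± 0.45) and MELK (2.46 ± 0.34), beside the proliferation antigen MKI67 (0.70 ± 0.22, adjusted p = 0.0385). Their median was 2.54, 1.93, 2.06 and 1.90 in the pairs of replicates 1 to 4, and 26 rose and 0 fell adjusted over the list alone. Contractile smooth muscle genes rose in 0 and fell in 15 of 18 cases, with a median difference of -2.06 (adjusted p = 3.84e-09, and adjusted p = 0.503 with an estimated correlation). The smooth muscle myosin heavy chain MYH11 fell by 3.23 ± 0.74 (adjusted p = 0.00807), phospholamban (PLN) by 3.37 ± 0.66 and smooth muscle actin (ACTA2) by 2.20 ± 0.65. Of these genes, 0 rose and 17 fell adjusted over the list alone. Monocyte and macrophage markers rose in 8 and fell in 0 of 22 cases, with a median difference of 0.72 (adjusted p = 0.00105, and adjusted p = 0.537 with an estimated correlation). The scavenger receptor MSR1 rose by 2.50 ± 0.39, the phagosomal metal transporter SLC11A1 by 3.16 ± 0.57 and CD163 by 1.35 ± 0.28, and 10 rose and 0 fell adjusted over the list alone.

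Endothelial markers rose in 6 and fell in 0 of 14 cases, with a median difference of 0.38 (adjusted p = 0.0123, and adjusted p = 0.503 with an estimated correlation). The VEGF receptor KDR (2.13 ± 0.33) and the transcription factor SOX18 (1.20 ± 0.20) rose, and 6 rose and 0 fell adjusted over the list alone. PECAM1, an adhesion molecule of endothelium, stood at 0.19 ± 0.26 (adjusted p = 0.710) and the leukocyte gene PTPRC at 0.26 ± 0.20 (adjusted p = 0.434). Matrix proteases and inhibitors rose in 7 and fell in 0 of 23 cases, with a median difference of 0.34 (adjusted p = 0.0123, and adjusted p = 0.503 with an estimated correlation, the median being 0.62 without replicate 4). Urokinase (PLAU, 2.38 ± 0.44), the protease inhibitor SERPINE2 (2.15 ± 0.38) and cathepsin B (CTSB, 1.20 ± 0.21) were examples, and 7 rose and 1 fell adjusted over the list alone. Endoplasmic reticulum folding genes rose in 8 and fell in 2 of 16 cases, with a median difference of 0.60 (adjusted p = 0.0119, and adjusted p = 0.503 with an estimated correlation). CRELD2 rose by 1.72 ± 0.29 and the chaperone calreticulin (CALR) by 1.19 ± 0.22, and 9 rose and 3 fell adjusted over the list alone. Hypoxia and glycolysis genes rose in 5 and fell in 0 of 14 cases, with a median difference of 0.40 (adjusted p = 0.0104, and adjusted p = 0.503 with an estimated correlation). The glucose transporter SLC2A1 rose by 1.28 ± 0.33, and 5 rose and 0 fell adjusted over the list alone.

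Fibrillar collagen genes rose in 4 and fell in 2 of 25 cases (4 rose and 2 fell adjusted over the list alone), with no call as a list (median 0.44, adjusted p = 0.296). COL1A1, the main collagen of scar matrix, stood at -0.50 ± 0.36 (adjusted p = 0.404), while the matrix glycoprotein TNN rose by 3.09 ± 0.74. Adipocyte markers gave no call (median -0.19, adjusted p = 0.296). A group of 5 lists was called in 0 of the 12 comparisons. Of these, growth factors and receptors rose in 4 and fell in 5 of 23 cases (5 rose and 6 fell adjusted over the list alone; adjusted p = 0.952), and TGF-beta and BMP genes rose in 3 and fell in 6 of 24 cases (4 rose and 8 fell adjusted over the list alone; adjusted p = 0.700). The others were B and plasma cell (adjusted p = 0.505), Schwann cell and nerve (adjusted p = 0.375) and blood cell markers (adjusted p = 0.932). The TGF-beta list had a median of 0.03, a mean of -0.51 and a downward test, so that these differed in sign. The neural gene CDH19, not well above background in 4 of 4 anastomosis samples, was at least 2.20-fold lower (adjusted p = 0.0201). Such bounds are set against the floor of the dim group and are open to dye bias. Of the 7 housekeeping genes, 5 were measured. ACTB (0.87 ± 0.23, adjusted p = 0.0178), HPRT1 (1.54 ± 0.26, adjusted p = 0.00146) and RPL4 (0.38 ± 0.10, adjusted p = 0.0131) were higher, RPL4 missing with processed signals (0.29, adjusted p = 0.166). PPIA (0.14 ± 0.15) did not pass, nor did YWHAZ (-0.32 ± 0.12), which turned with median centring (0.58, adjusted p = 0.0176).

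In limma, 6445 features passed an adjusted p of 0.05 at the anastomosis at day 5, 3009 higher and 3436 lower. Of these, 2336 differed by at least 2-fold (948 higher, 1388 lower), and 1746 of the passing features had a symbol. The count was 3803 without replicate 3, 2393 without replicate 4 and 2285 with no replicate block. It was 2 with replicates 1 and 2 alone and 3959 with replicates 3 and 4 alone. Median centring in place of loess moved the median of all genes by 0.101 and gave 80.7% of calls higher, against 46.7%. MYH11 (-2.05, adjusted p = 0.0527) and ACTA2 (-0.72, adjusted p = 0.427; -1.73, adjusted p = 0.0658 with single-channel quantiles) then missed, and PECAM1 (1.39, adjusted p = 4.12e-04) and PTPRC (1.02, adjusted p = 0.00144) passed. Of the 39 called genes named here, 3, 4, 3 and 11 lost their call without replicates 1 to 4, as did the hypoxia list without replicate 1 (adjusted p = 0.0591, median 0.25).

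**Figure D1:**
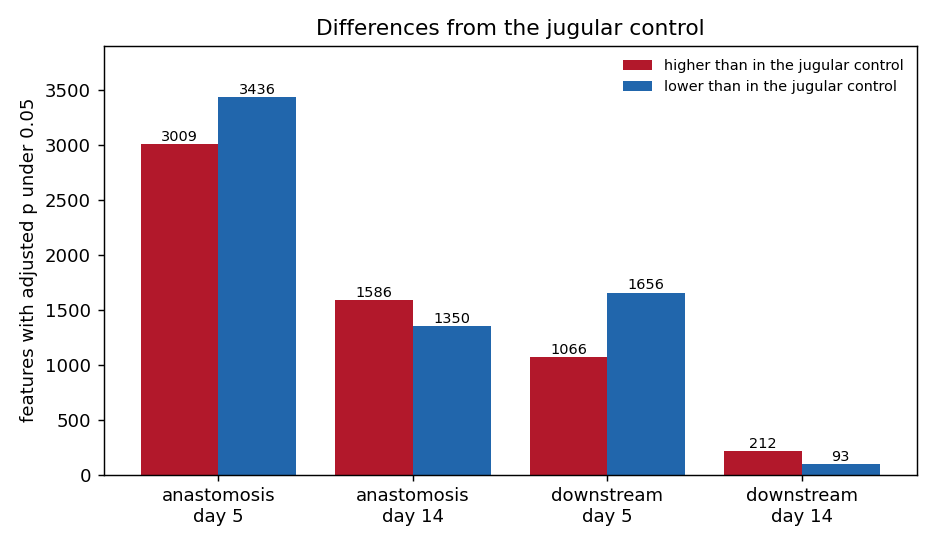
Bars give the number of features (vertical axis) with an adjusted p under 0.05 in limma that were higher (red) or lower (blue) than in the jugular control, for the anastomosis and the downstream vein at each day, n = 4 per group. The anastomosis at day 5 had 3009 higher and 3436 lower features and the downstream vein at day 14 had 212 and 93.

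At day 14 the anastomosis was again set against the jugular control. THBS4, a thrombospondin of the matrix, had the largest rise, 6.60 ± 0.91 (adjusted p = 0.00178). It was followed by SPP1 (5.12 ± 1.06), the acid phosphatase ACP5 of osteoclasts and macrophages (4.25 ± 0.68), TNN (4.23 ± 0.74) and CXCL14 (4.11 ± 0.77). TMEM158 (3.95 ± 0.31), the calpain CAPN6 (3.89 ± 0.76) and the cell fusion receptor DCSTAMP (3.38 ± 0.80) came next (adjusted p from 4.81e-05 to 0.0205 after THBS4). The fibrillar collagen COL11A1, not well above background in 4 of 4 control samples, was at least 9.93-fold higher (adjusted p = 0.00188), and periostin (POSTN) rose by 2.95 ± 0.49. Falls were largest for TP23 (-4.38 ± 0.44), the metallothionein MT1A (-4.14 ± 0.91), SCARA5 (-3.67 ± 0.51) and PPL (-3.44 ± 0.46). KCNAB1 (-3.43 ± 0.86), the heat shock gene HSPA6 (-3.29 ± 0.79), MYOC (-3.18 ± 0.86, or -1.99 and adjusted p = 0.187 without replicate 2) and SKIL, a repressor of SMAD signalling (-3.09 ± 0.61), fell too (adjusted p from 6.19e-04 to 0.0355 over these 8).

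Monocyte and macrophage markers rose in 10 and fell in 0 of 22 cases, with a median difference of 1.16 (adjusted p = 4.06e-10, and adjusted p = 0.211 with an estimated correlation). MSR1 (2.78 ± 0.39), VSIG4 (1.56 ± 0.26) and CD68 (1.86 ± 0.32) were among them, and 19 rose and 0 fell adjusted over the list alone. Matrix proteases and inhibitors rose in 6 and fell in 0 of 23 cases, with a median difference of 0.92 (adjusted p = 3.67e-05, and adjusted p = 0.171 with an estimated correlation). They included CTSB (1.68 ± 0.21), SERPINE2 (2.67 ± 0.38) and the collagen-degrading cathepsin CTSK (1.04 ± 0.18), and 10 rose and 0 fell adjusted over the list alone. Fibrillar collagen and matrix genes rose in 8 and fell in 0 of 25 cases, with a median difference of 0.86 (adjusted p = 4.12e-04, and adjusted p = 0.477 with an estimated correlation, the median being 0.50 without replicate 1). The medians of replicates 1 to 4 were 0.84, 1.74, 0.01 and -0.13, and 8 rose and 0 fell adjusted over the list alone. In the replicate 2 control, which stood apart, 14 of the 25 lay below each of the other 3 controls (median difference -1.17). Complement and coagulation genes rose in 7 and fell in 1 of 27 cases, with a median difference of 0.68 (adjusted p = 0.00215, and adjusted p = 0.211 with an estimated correlation). Complement C3 rose by 2.80 ± 0.62 and the coagulation inhibitor TFPI by 1.47 ± 0.18, and 13 rose and 2 fell adjusted over the list alone. Endothelial markers rose in 5 and fell in 0 of 14 cases, with a median difference of 0.33 (adjusted p = 0.00400, and adjusted p = 0.477 with an estimated correlation, the median being 0.57 without replicate 1). KDR rose by 1.68 ± 0.33, and 5 rose and 1 fell adjusted over the list alone.

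Contractile smooth muscle genes rose in 0 and fell in 2 of 18 cases, with a median difference of -1.32 (adjusted p = 6.27e-07, and adjusted p = 0.477 with an estimated correlation, the median being -2.04 without replicate 2). PDLIM3, a protein of actin filaments, fell by 2.65 ± 0.62, and MYH11 stood at -2.46 ± 0.74, which missed (adjusted p = 0.0535). MYH11 passed with processed signals (-2.54, adjusted p = 0.0447), no background correction (-2.45, adjusted p = 0.0470) and single-channel quantiles (-2.36, adjusted p = 0.0472). Of the contractile genes, 0 rose and 12 fell adjusted over the list alone. Their pair medians were -1.23, 0.92, -2.46 and -2.25, and those of the adipocyte markers 0.08, -2.86, 3.06 and 0.27 (no call, adjusted p = 0.621). In the jugular control of replicate 2 at day 14, 17 of 18 contractile genes lay below and 21 of 22 adipocyte markers above each of the other 3 controls. At the anastomosis at day 14 the adipocyte hormone gene ADIPOQ stood at 16.42 in replicate 3 and at 8.99, 8.40 and 11.94 in replicates 1, 2 and 4. Skeletal muscle markers rose in 0 and fell in 4 of 23 cases, with a median difference of -0.20 (adjusted p = 0.0240, and adjusted p = 0.248 with an estimated correlation), and 1 rose and 7 fell adjusted over the list alone. Lymph node markers rose in 1 and fell in 0 of 10 cases, with a median difference of 0.50 (adjusted p = 0.0371, and adjusted p = 0.477 with an estimated correlation). The lymphatic chemokine CCL21 was the gene that rose (3.13 ± 0.70), and 2 rose and 0 fell adjusted over the list alone. The cell cycle list, with 0 of 27 members past the threshold, gave no call (median 0.44, adjusted p = 0.0750).

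The test called 2936 features at the anastomosis at day 14, 1586 higher and 1350 lower, with 1019 past 2-fold (545 higher, 474 lower). There were 1697, 1611 and 139 without replicates 1, 3 and 4, 575 with no replicate block and 57 with only the samples compared. Replicates 1 and 2 alone gave 1 and replicates 3 and 4 alone 3227. With median centring the median of all genes moved by 0.162 and 74.8% of calls were higher, against 54.0%. Of the 29 called genes named for this day, 6, 3, 6 and 19 lost their call without replicates 1 to 4. So did the collagen list without replicate 2 (adjusted p = 0.0705, median 0.37), the endothelial list without replicate 4 (adjusted p = 0.120, median 0.13) and the lymph node list without replicates 1 and 4 (adjusted p of 0.0655 and 0.0575).

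Downstream of the anastomosis, the vein at day 5 was compared with the same jugular controls. SPP1 was higher by 4.10 ± 1.06 (adjusted p = 0.0317), THBS4 by 3.46 ± 0.91, CAPN6 by 3.44 ± 0.76 and ACP5 by 2.76 ± 0.68. TMEM158 rose by 2.75 ± 0.31, the sulphotransferase SULT1A3 by 2.73 ± 0.63, SLC11A1 by 2.62 ± 0.57 and CCNB1 by 2.50 ± 0.56 (adjusted p from 0.00156 to 0.0343 after SPP1). Lower genes were KCNAB1 (-3.68 ± 0.86), MYOC (-3.55 ± 0.86), SCARA5 (-3.09 ± 0.51) and the actin regulator CAP2 (-2.98 ± 0.72). SPARCL1 (-2.97 ± 0.67), MYH11 (-2.94 ± 0.74), PLN (-2.91 ± 0.66) and PPL (-2.90 ± 0.46) were also lower (adjusted p from 0.00528 to 0.0296 over these 8). Cell cycle genes rose in 14 and fell in 0 of 27 cases, with a median difference of 1.15 (adjusted p = 7.18e-12, and adjusted p = 0.369 with an estimated correlation). CDK1 rose by 2.31 ± 0.49 and TOP2A by 2.06 ± 0.45, and 19 rose and 0 fell adjusted over the list alone. The medians of the pairs of replicates 1 to 4 were 0.32, 1.54, 1.71 and 1.64.

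Contractile genes rose in 0 and fell in 10 of 18 cases, with a median difference of -1.83 (adjusted p = 1.67e-10, and adjusted p = 0.369 with an estimated correlation), and 0 rose and 18 fell adjusted over the list alone. Macrophage markers rose in 6 and fell in 0 of 22 cases, with a median difference of 0.89 (adjusted p = 8.08e-07, and adjusted p = 0.369 with an estimated correlation). MSR1 rose by 2.19 ± 0.39, and 9 rose and 0 fell adjusted over the list alone. Proteases and inhibitors rose in 5 and fell in 0 of 23 cases, with a median difference of 0.40 (adjusted p = 0.00292, and adjusted p = 0.369 with an estimated correlation). PLAU rose by 2.42 ± 0.44, and 5 rose and 0 fell adjusted over the list alone. Endothelial markers rose in 5 and fell in 0 of 14 cases, with a median difference of 0.42 (adjusted p = 0.00292, and adjusted p = 0.369 with an estimated correlation). KDR rose by 1.70 ± 0.33 and the junction cadherin CDH5 by 1.18 ± 0.29, and 6 rose and 0 fell adjusted over the list alone. Complement genes rose in 5 and fell in 1 of 27 cases, with a median difference of 0.31 (adjusted p = 0.00895, and adjusted p = 0.369 with an estimated correlation). TFPI rose by 2.09 ± 0.18, factor D (CFD) stood at -2.04 ± 0.38, and 7 rose and 2 fell adjusted over the list alone. Mitochondrial energy genes rose in 1 and fell in 4 of 25 cases, with a median difference of -0.23 (adjusted p = 0.0420, and adjusted p = 0.717 with an estimated correlation). PDK4 fell (-2.28 ± 0.62), and 1 rose and 4 fell adjusted over the list alone.

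For the downstream vein at day 5, 2722 features passed in limma, 1066 higher and 1656 lower, 930 of them past 2-fold (337 and 593). The count was 4415, 371, 6 and 2 without replicates 1 to 4 and 324 with no replicate block. With replicates 1 and 2 alone it was 0 (2494 at an unadjusted p under 0.05) and with replicates 3 and 4 alone 3353. The share of higher calls, 39.2%, was 21.3% with loess and no between-array step and 83.1% with median centring. The latter moved the median of all genes by 0.112 and turned the direction of the mitochondrial list, and MYH11 (-1.89, adjusted p = 0.0819) and PDK4 (-1.64, adjusted p = 0.0755) then missed. Without replicates 1 to 4, 0, 20, 23 and 24 of the 25 called genes named for this comparison lost their call. Without replicate 1 so did the complement (adjusted p = 0.159) and mitochondrial lists (adjusted p = 0.123).

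The downstream vein was then set against the control of day 14. THBS4 (5.27 ± 0.91), RGS5, a G protein regulator of pericytes and smooth muscle (2.92 ± 0.51), TMEM158 (2.24 ± 0.31) and FHL5 (1.93 ± 0.39) had the largest rises. The chemokine CXCL12 (1.91 ± 0.42), complement factor I (CFI, 1.75 ± 0.24), SERPINE2 (1.74 ± 0.38) and KDR (1.72 ± 0.33) followed (adjusted p from 0.00688 to 0.0477 over these 8). Lower were TP23 (-3.37 ± 0.44), the heat shock gene HSP70.2 (-2.53 ± 0.53), the neutrophil chemokine receptor CXCR2 (-1.42 ± 0.30) and CD101 (-1.29 ± 0.27). The HSP90 co-chaperones AHSA1 (-1.0 ± 0.16) and FKBP4 (-0.79 ± 0.16), the mevalonate pathway kinase PMVK (-0.86 ± 0.14) and ZNF134 (-0.78 ± 0.13) also fell (adjusted p from 0.00585 to 0.0432). SPP1 stood at 3.38 ± 1.06 and missed (adjusted p = 0.144). Endothelial markers rose in 1 and fell in 0 of 14 cases, with a median difference of 0.73 (adjusted p = 1.33e-06, and adjusted p = 0.157 with an estimated correlation), and 10 rose and 0 fell adjusted over the list alone. Complement genes rose in 2 and fell in 0 of 27 cases, with a median difference of 0.45 (adjusted p = 8.02e-05, and adjusted p = 0.157 with an estimated correlation, the median being 0.29 without replicate 1). TFPI rose by 1.63 ± 0.18, and 8 rose and 0 fell adjusted over the list alone. Proteases rose in 2 and fell in 0 of 23 cases, with a median difference of 0.41 (adjusted p = 0.00191, and adjusted p = 0.207 with an estimated correlation, the median being 0.65 and 0.22 without replicates 2 and 3). CTSB rose by 1.02 ± 0.21, and 3 rose and 0 fell adjusted over the list alone.

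Macrophage markers were called higher downstream at day 14 as a list, with 0 of 22 members past the threshold over all genes or adjusted over the list alone. The list median was 0.42, or 0.72 and 0.69 without replicates 1 and 2 (adjusted p = 0.00575, and adjusted p = 0.862 with an estimated correlation). The contractile list was called lower with 0 of 18 members past either threshold. Its median was -0.92, or -1.58 and -0.49 without replicates 2 and 3 (adjusted p = 3.68e-06, and adjusted p = 0.703 with an estimated correlation). The contractile medians of the pairs were -0.23, 0.28, -2.36 and -2.05, the second being the pair of the jugular control with few contractile and many adipocyte transcripts. Those of the adipocyte markers were -0.20, -0.41, -0.05 and 2.44 (no call, adjusted p = 0.334), with ADIPOQ at 7.21, 16.77, 12.06 and 15.77 in downstream replicates 1 to 4. The cell cycle list was not called (0 rose and 0 fell; median -0.08, adjusted p = 0.402). In limma 305 features passed, 212 higher and 93 lower, 104 of them past 2-fold (74 and 30). This became 149, 14 and 4 without replicates 1, 3 and 4 and 11 with no replicate block. It was 0 with replicates 1 and 2 alone (2631 at an unadjusted p under 0.05) and 1796 with replicates 3 and 4 alone. On the first 2 principal components the downstream sample of replicate 1 lay at -61.2 and -26.8 and its control at -59.3 and -28.6. With only the samples compared the count was 0 (3440 at an unadjusted p under 0.05). The share of higher calls, 69.5%, was 33.3% with loess alone and 77.3% with median centring, which moved the median of all genes by 0.193. CXCR2, AHSA1, PMVK, FKBP4 and ZNF134 then missed and SPP1 passed (4.03, adjusted p = 0.0140). With processed signals CXCL12 (adjusted p = 0.0511), CXCR2 (0.0551), CD101 (0.0806), FKBP4 (0.0735) and CTSB (0.0969) missed. CXCL12 (0.0535) and SERPINE2 (adjusted p = 0.0551) missed with loess alone, and FKBP4 with single-channel quantiles (adjusted p = 0.0636). Of the 18 called genes named for the downstream vein at day 14, 8, 6, 18 and 18 lost their call without replicates 1 to 4. The macrophage list lost its call without replicates 3 and 4 (adjusted p of 0.209 and 0.328, medians 0.17 and 0.19).

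**Figure D2:**
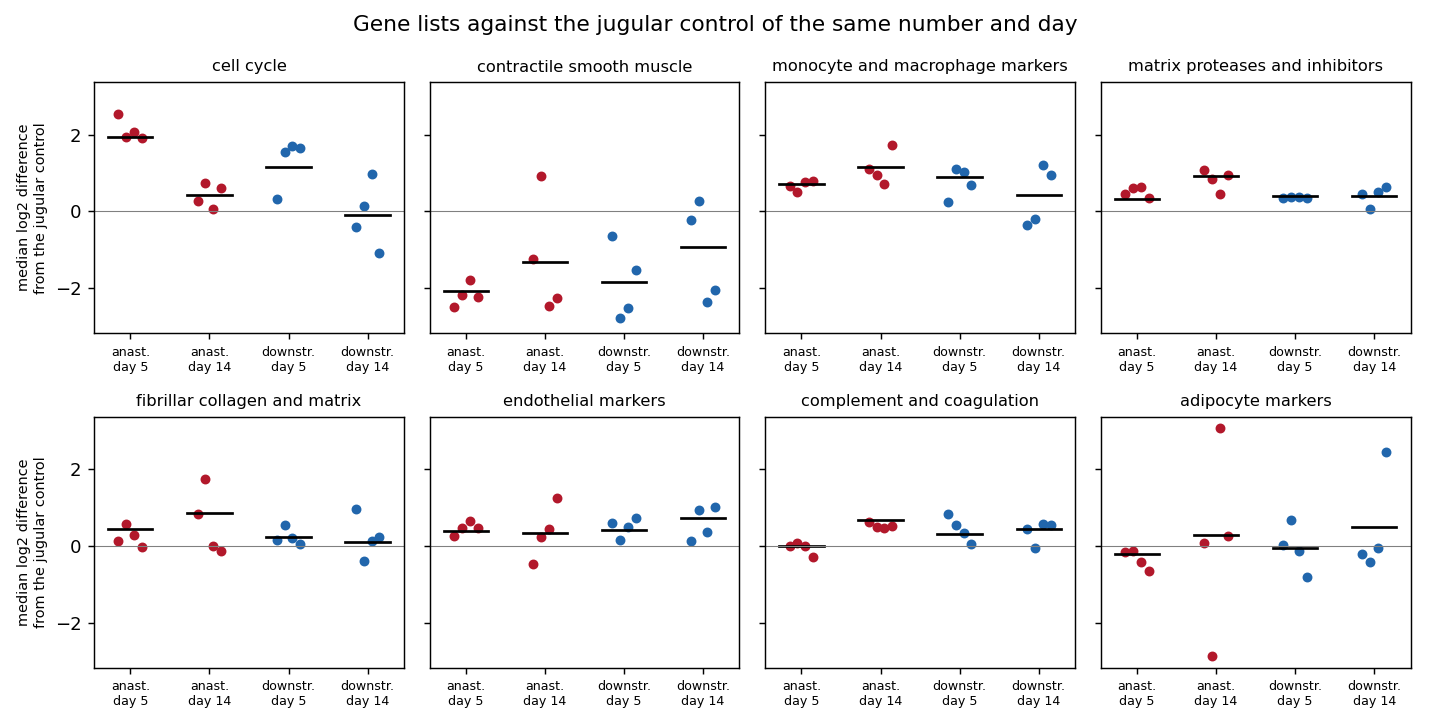
Each panel shows a gene list, with the median log2 difference from the jugular control of the same number and day on the vertical axis, a point per replicate pair (1 to 4 from left to right) and a black line at the median of the fitted differences. The cell cycle medians at the anastomosis at day 5 were 2.54, 1.93, 2.06 and 1.90, and the adipocyte median of replicate 2 at day 14 was -2.86 at the anastomosis.

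Both graft sites were compared with the same jugular controls, so their calls share the controls' chance values. At day 5, 2332 features passed at both sites (827 higher, 1505 lower, 0 opposite). Independent lists would share 96.3 higher and 171 lower features. In 20 draws of unchanged groups, in which every sample including the controls was simulated gene by gene, at most 0 features were shared. These draws hold no correlation between genes, so their 0 on either day does not show that the overlap exceeds what shared controls give. TMEM158 and SCARA5 were among the genes called at both sites on that day. The fold changes had r = 0.904 across genes, which are not independent replicates (simulated 0.498), and a covariance of 0.234 (simulated 0.0218). At day 14, 243 features passed at both sites (169 higher, 74 lower, 0 opposite). Independent lists would share 10.1 and 3.77, and the simulation gave at most 0. Across genes r was 0.731 (simulated 0.499) and the covariance 0.111 (simulated 0.0218). With the controls split into sets of 2, in 6 ways, 0 to 2835 features were shared at day 5 and 0 at day 14. In these splits r was at least 0.678 at day 5 and 0.108 at day 14.

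The contrast of the anastomosis with the downstream vein addressed the difference between vein regions named in the study's title, with both groups in Cy5. At day 5 cell cycle genes (median 0.89, or 0.35 without replicate 1, adjusted p = 1.15e-12), endoplasmic reticulum folding genes (median 0.31, adjusted p = 0.00619) and hypoxia genes (median 0.18, or 0.36 without replicate 4, adjusted p = 0.0413) were called higher at the anastomosis as lists. Complement (median -0.40, or -0.22 without replicate 1, adjusted p = 2.85e-04) and interferon genes (median -0.39, or -0.59 without replicate 3, adjusted p = 9.88e-04) were called lower. These 5 lists gave adjusted p from 0.239 to 0.939 with an estimated correlation, and each had 0 members past the threshold and 0 adjusted over the list alone. The cell cycle medians of the pairs were 2.26, 0.53, 0.23 and 0.39. Without replicate 1 the folding (adjusted p = 0.131, median 0.19) and hypoxia lists (adjusted p = 0.830, median 0.06) lost their call. Without replicate 2 the interferon (adjusted p = 0.135, median -0.16), folding (adjusted p = 0.0598) and hypoxia lists (adjusted p = 0.0866) did. For single features limma called 0 at day 5 (3316 at an unadjusted p under 0.05). The 5 symbol genes with the smallest p missed (adjusted p = 0.426 for each). They were the death-associated kinase DAPK1 (-1.05 ± 0.19), SCARA5 (-2.75 ± 0.51), the lymphatic transcription factor PROX1 (-1.30 ± 0.24), tenascin X (TNXB, -1.83 ± 0.35) and the chondroitin synthase CHSY3 (0.97 ± 0.19).

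At day 14 macrophage markers were called higher at the anastomosis than downstream (median 0.85, or 0.53 without replicate 1, adjusted p = 2.14e-08, and adjusted p = 0.806 with an estimated correlation). Over all genes 0 of 22 passed, and 10 adjusted over the list alone. MSR1 stood at 2.06 ± 0.39 (adjusted p = 0.110), CD68 at 1.22 ± 0.32 and CD163 at 0.97 ± 0.28, and the pair medians were 1.29, 1.07, -0.13 and 0.64. Adipocyte markers had pair medians of 0.30, -2.34, 2.87 and -1.63 (no call, adjusted p = 0.708), and those of the fibrillar collagen and protease lists were 0.03, 2.07, -0.01 and -0.17 and 0.76, 0.58, -0.05 and 0.12. ADIPOQ stood at 8.40 at the anastomosis against 16.77 downstream in replicate 2 and at 16.42 against 12.06 in replicate 3. Cell cycle genes (median 0.55, or 0.99 without replicate 3, adjusted p = 8.89e-04), fibrillar collagen genes (median 0.40, or 0.65 without replicate 1, adjusted p = 0.00236) and proteases (median 0.49, adjusted p = 0.0206) were also called higher. Interferon (median -0.27, or -0.44 and -0.45 without replicates 1 and 3, adjusted p = 0.00820) and flow-responsive endothelial genes (median -0.40, or -0.60 without replicate 3, adjusted p = 0.0336) were called lower, and these 5 lists gave adjusted p from 0.806 to 0.878 with an estimated correlation. Adjusted over the list alone, 0, 1 and 4 members of the first 3 rose and 0 and 0 of the last 2 fell. Without replicate 2 the test of the collagen list turned downward (adjusted p = 0.940, median 0.12), and the interferon (adjusted p = 0.107), protease (adjusted p = 0.0754, median 0.13) and flow lists (adjusted p = 0.209, median -0.25) were not called. Without replicate 4 the cell cycle (adjusted p = 0.660, median 0.13), interferon (adjusted p = 0.0942) and flow lists (adjusted p = 0.158) were not called, nor was the protease list without replicate 1 (adjusted p = 0.171, median 0.19). For single features limma called 0 (4726 at an unadjusted p under 0.05), but 440 without replicate 3 and 106 with loess and no between-array step. The smallest p among symbol genes, all missing (adjusted p from 0.109 to 0.110), were of the efflux pump ABCB1 (-1.0 ± 0.16), PHYHIPL (2.45 ± 0.43), TMEM158 (1.71 ± 0.31), KIAA1324L (-1.74 ± 0.32) and COL11A1 (2.60 ± 0.48). These 5 genes (adjusted p at most 0.0499) and MSR1 (2.21, adjusted p = 0.0449) passed with loess alone.

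**Figure D3:**
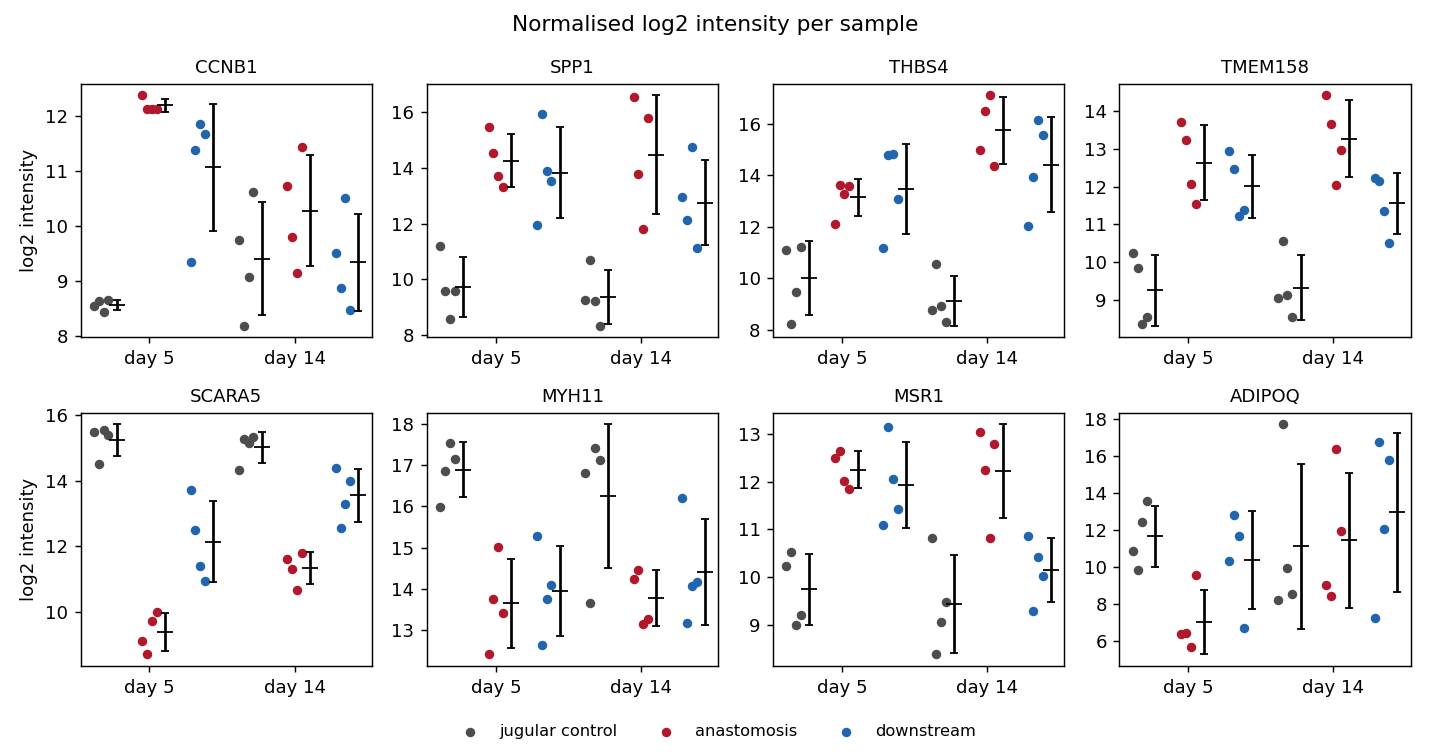
Normalised log2 intensity (vertical axis) of 8 genes in each sample, by day and site (grey, jugular control; red, anastomosis; blue, downstream), with the mean and SD of the 4 samples of a group beside the points. CCNB1 at day 5 was 12.20 ± 0.12 at the anastomosis and 8.57 ± 0.10 in the control, and ADIPOQ in the jugular control of replicate 2 at day 14 was 17.75 against at most 9.92 in the other day 14 controls.

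Whether a difference between sites itself changed from day 5 to day 14 was tested as an interaction, in which 0 members of any list passed over all genes. The cell cycle list was lower at day 14 than at day 5, relative to the control, at the anastomosis (median -1.68, adjusted p = 2.73e-27, and adjusted p = 0.264 with an estimated correlation). Of its members, 0 rose and 23 fell adjusted over the list alone. Downstream it changed likewise (median -1.42, or -0.86 without replicate 4, adjusted p = 8.59e-19, and adjusted p = 0.860 with an estimated correlation), and 0 rose and 15 fell adjusted over the list alone. These changes differed between the graft sites (median -0.26, or -0.77 without replicate 4, adjusted p = 0.0207, and adjusted p = 0.917 with an estimated correlation), a call lost without replicate 1 (adjusted p = 0.756, median 0.04) and replicate 3 (adjusted p = 0.764, median -0.09). The macrophage list was called upward at the anastomosis (median 0.27, adjusted p = 0.0203, and adjusted p = 0.672 with an estimated correlation), which was lost without replicates 1 and 4 (adjusted p of 0.0688 and 0.158, medians 0.25 and 0.09). Downstream it was called downward (median -0.47, or -0.71 without replicate 3, adjusted p = 0.00559, and adjusted p = 0.943 with an estimated correlation), which was lost without replicate 2 (adjusted p = 0.489, median -0.07). The difference between these changes was called (median 0.83, or 0.55 without replicate 2, adjusted p = 6.86e-11, and adjusted p = 0.377 with an estimated correlation), and 5 rose and 0 fell adjusted over the list alone. The fibrillar collagen list was called upward against the control at the anastomosis (median 0.56, adjusted p = 0.00762, and adjusted p = 0.672 with an estimated correlation) but not without replicate 2 (adjusted p = 0.241, median 0.37). It was also called upward relative to the downstream vein (median 0.61, adjusted p = 5.72e-04, and adjusted p = 0.722 with an estimated correlation), again not without replicate 2 (adjusted p = 0.805, median -0.06).

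For the lists that follow, 0 members passed adjusted over the list alone, except 1 falling gene each among the cytokines and the neutrophil markers. The complement list was called upward at the anastomosis against the control (median 0.48, adjusted p = 0.00762) and against the downstream vein (median 0.32, adjusted p = 0.00600), with adjusted p of 0.276 and 0.377 with an estimated correlation. Both calls were lost without replicate 1 (adjusted p of 0.0550 and 0.216, medians 0.24 and 0.06). The protease list was called upward at the anastomosis relative to the downstream vein (median 0.24, or 0.64 without replicate 3, adjusted p = 0.0207, and adjusted p = 0.495 with an estimated correlation), which was lost without replicates 1, 2 and 4 (adjusted p of 0.205, 0.141 and 0.0847, medians 0.13, 0.17 and 0.16). The folding list was called downward at the anastomosis (median -0.29, or -0.53 without replicate 2, adjusted p = 1.17e-04, and adjusted p = 0.264 with an estimated correlation). So it was downstream (median -0.32, or -0.49 without replicate 2, adjusted p = 0.0259, and adjusted p = 0.943 with an estimated correlation) except without replicate 4 (adjusted p = 0.417, median -0.19). The contractile list was called upward at the anastomosis (median 0.62, or 1.08 without replicate 3, adjusted p = 0.0274) and downstream (median 0.75, or 1.20 without replicate 4, adjusted p = 0.00559), with adjusted p of 0.737 and 0.943 with an estimated correlation. Without replicate 2, whose day 14 control carried few contractile transcripts, the first turned down (adjusted p = 0.728, median -0.049) and the second was not called (adjusted p = 0.909, median 0.08). Without replicate 1 the first was not called either (adjusted p = 0.0652). The adipocyte list was called upward at the anastomosis (median 0.73, or 2.03 without replicate 2, adjusted p = 0.0203, and adjusted p = 0.737 with an estimated correlation). This turned without replicate 3 (adjusted p = 0.364, median -0.15) and was not called without replicate 4 (adjusted p = 0.0963). Inflammatory cytokines (median -0.63, adjusted p = 0.0203), neutrophil markers (median -0.21, or -0.33 and -0.36 without replicates 3 and 4, adjusted p = 0.0404) and hypoxia genes (median -0.22, adjusted p = 0.0404) were called lower at the anastomosis, each at adjusted p = 0.672 with an estimated correlation. Each was lost without replicate 1 (adjusted p of 0.0891, 0.0688 and 0.204, medians -0.45, -0.23 and -0.15) and replicate 2 (adjusted p of 0.212, 0.439 and 0.241, medians -0.29, -0.13 and -0.16), and the cytokines also without replicate 3 (adjusted p = 0.141, median -0.21).

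In limma the interaction called 0 features for the anastomosis and 0 for the downstream vein against the control, and 0 between the graft sites. At an unadjusted p under 0.05 these were 2768, 2509 and 1390, the last fewer than chance gives. Among symbol genes, the 5 smallest p in the first, all missing, were of the complement inhibitor C4BPA (2.91 ± 0.46), NPL (0.99 ± 0.19), the pigment and osteoclast transcription factor MITF (1.5 ± 0.30), GPR1 (2.07 ± 0.41) and the protease inhibitor CST3 (1.5 ± 0.31), with adjusted p from 0.339 to 0.363. Those in the second were LRRC49 (-0.78 ± 0.16), CEP120 (0.81 ± 0.16), AMH (-0.42 ± 0.09), WWP1 (0.81 ± 0.18) and N4BP2L1 (1.12 ± 0.26), at adjusted p of at least 0.661. The third had SOX9 (1.07 ± 0.22), WDR63 (1.62 ± 0.39), CPSF6 (-0.56 ± 0.14), DAPK1 (1.05 ± 0.27) and ABCB1 (-0.83 ± 0.22), at adjusted p of at least 0.984.

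Between days within a site, day 14 was set against day 5 in the 8 samples of that site, with scan and slide differing between the days for replicates 1 and 2. At the anastomosis the cell cycle list was lower at day 14 (median -1.44, adjusted p = 1.35e-26, and adjusted p = 0.20 with an estimated correlation). Of its 27 members, 0 passed over all genes and 21 adjusted over the list alone, with CCNB1 at -1.91 ± 0.43 (adjusted p = 0.32) and TOP2A at -1.51 ± 0.34. Folding (median -0.52, adjusted p = 1.07e-08), collagen processing (median -0.60, adjusted p = 0.00344) and hypoxia genes (median -0.33, adjusted p = 0.00592) were also called lower. Adipocyte markers (median 1.49, or 0.70 without replicate 3, adjusted p = 1.05e-08), interferon (median 0.30, adjusted p = 1.45e-06), macrophage (median 0.32, or 0.52 without replicate 3, adjusted p = 0.00812), lymph node (median 0.37, or 0.56 without replicate 3, adjusted p = 0.00817) and complement genes (median 0.16, or 0.33 without replicate 3, adjusted p = 0.0216) were called higher. In replicates 1 to 4 ADIPOQ stood at 6.37, 6.38, 5.66 and 9.58 at day 5 and 8.99, 8.40, 16.42 and 11.94 at day 14. These 8 lists gave adjusted p from 0.0818 to 0.399 with an estimated correlation. Hypoxia lost its call without replicate 1 (adjusted p = 0.0783, median -0.19), macrophage without replicate 4 (adjusted p = 0.0591, median 0.12) and complement without replicates 2 and 4 (adjusted p of 0.173 and 0.0796, medians 0.10 and 0.16). For single features limma called 2, 1 higher and 1 lower (2739 at an unadjusted p under 0.05). CCBE1, a gene of lymphatic vessel growth, fell from 11.85 ± 0.23 to 10.29 ± 0.11 (-1.56 ± 0.14, adjusted p = 0.0471), and the other was a probe with no symbol. CCBE1 lost its call without each of replicates 1 to 4 (adjusted p of 0.586, 0.285, 0.370 and 0.253) and under each of 5 other scalings (adjusted p from 0.0647 to 0.540). ADM5 (-1.54 ± 0.17, adjusted p = 0.0829) and the lipid transporter ABCA8 (2.16 ± 0.24) missed.

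In the downstream vein the cell cycle list was lower at day 14 too (median -1.09, adjusted p = 1.41e-20, and adjusted p = 0.228 with an estimated correlation). Folding (median -0.38, adjusted p = 8.47e-06), collagen processing (median -0.55, adjusted p = 0.00179), macrophage (median -0.34, or -0.64 without replicate 3, adjusted p = 0.00195), hypoxia (median -0.31, adjusted p = 0.00278) and fibrillar collagen genes (median -0.26, or -0.49 and -0.41 without replicates 1 and 4, adjusted p = 0.0145) were called lower as lists. Adipocyte (median 1.24, or 0.78 and 0.67 without replicates 2 and 4, adjusted p = 5.86e-07), T and NK cell (median 0.46, adjusted p = 0.00179) and interferon genes (median 0.38, or 0.67 without replicate 1, adjusted p = 0.00506) were called higher, and 0 members of these lists passed over all genes or adjusted over the list alone. ADIPOQ in replicates 1 to 4 was 10.29, 12.84, 11.67 and 6.69 at day 5 and 7.21, 16.77, 12.06 and 15.77 at day 14. These 8 lists gave adjusted p from 0.0856 to 0.609 with an estimated correlation. Without replicate 2 collagen processing (adjusted p = 0.102, median -0.13) and macrophages (adjusted p = 0.0788, median -0.14) were not called and fibrillar collagen turned (adjusted p = 0.773, median 0.20). T and NK cells (adjusted p = 0.350, median 0.15) and interferon (adjusted p = 0.350, median 0.07) were lost without replicate 3, and hypoxia (adjusted p = 0.105, median -0.10) and interferon (adjusted p = 0.196, median 0.04) without replicate 4. In limma 0 features passed (1489 at an unadjusted p under 0.05, fewer than chance gives). MAP4K2 (1.14 ± 0.21), CAMK2N1 (0.83 ± 0.16), TP23 (2.73 ± 0.52), AIF1L (0.94 ± 0.18) and the fibroblast growth factor FGF7 (-1.21 ± 0.23) had the smallest p among symbol genes and missed (adjusted p = 0.900 for each).

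In the jugular control itself contractile (median -0.70, adjusted p = 9.31e-05), fibrillar collagen (median -0.36, or -0.69 and -0.63 without replicates 3 and 4, adjusted p = 0.00130), collagen processing (median -0.40, adjusted p = 0.00310) and Wnt genes (median -0.15, or -0.29 and -0.33 without replicates 1 and 4, adjusted p = 0.00585) were called lower at day 14. Called higher were cell cycle (median 0.24, or 0.14, 0.48 and 0.44 without replicates 1, 2 and 3, adjusted p = 9.31e-05), T and NK cell (median 0.36, or 0.56 without replicate 4, adjusted p = 0.0010), interferon (median 0.30, or 0.47 without replicate 4, adjusted p = 0.00310) and neutrophil genes (median 0.61, or 1.02 and 0.36 without replicates 3 and 4, adjusted p = 0.00556). So were adipocyte (median 0.63, or 0.96 without replicate 4, adjusted p = 0.00660), lymph node (median 0.21, or 0.32 without replicate 4, adjusted p = 0.0135) and cytokine genes (median 0.29, or 0.48 without replicate 1, adjusted p = 0.0234). These 11 lists gave adjusted p from 0.364 to 0.646 with an estimated correlation. Without replicate 2, whose day 14 control stood apart, the adipocyte list turned and was called lower (adjusted p = 3.88e-05, median -0.33) and interferon turned (adjusted p = 0.408, median -0.12). Contractile (adjusted p = 0.865, median -0.03), fibrillar collagen (adjusted p = 0.392, median -0.03), Wnt (adjusted p = 0.441, median 0.02) and T and NK cell genes (adjusted p = 0.873, median 0.02) were then not called. Neither were neutrophil (adjusted p = 0.865, median 0.03), lymph node (adjusted p = 0.201, median -0.01) and cytokine genes (adjusted p = 0.899, median 0.02). The lymph node list was also lost without replicate 1 (adjusted p = 0.164, median 0.13), the cytokines without replicate 3 (adjusted p = 0.148, median 0.12) and the cell cycle list without replicate 4 (adjusted p = 0.276, median 0.08). In limma 0 features passed (637 at an unadjusted p under 0.05, fewer than chance gives). The smallest p among symbol genes were of C4BPA (-1.29 ± 0.21), LRRTM4 (-0.81 ± 0.15), CXCL16 (1.12 ± 0.22), TP23 (4.14 ± 0.80) and LTA (0.59 ± 0.12), all missing (adjusted p = 1.000). With an estimated correlation, 0 of the 86 list calls made in the 12 comparisons held.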

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

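The tests of dye bias, of the share of smooth muscle cells and of adipose tissue, and SCARA5, SPP1 and THBS4 as a test of exchanged labels, were chosen after the results were seen. The share of genes that kept their direction and the 35 splits of 8 values into 4 and 4 were set before.

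The cell cycle list was higher at the anastomosis at day 5 than in the control (median 1.93). Dye bias as the whole cause would shift it alike on both days, since the anastomosis was Cy5 throughout, but the list median of the difference changed from day 5 to day 14 by -1.77 on average (SD 0.43, -2.36 to -1.39 over the 4 numbers), which argued against it. A lower share of smooth muscle cells alone would raise the genes of other cell types alike, but the cell cycle median exceeded the endothelial median by 1.65 (SD 0.43, 1.41 to 2.29), which argued against that too. The site itself, as the labels name it, may be the cause and was not tested apart from what was sampled with it.

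The contractile smooth muscle list was lower at the anastomosis at day 5 (median -2.06). The endothelial and adipocyte medians moved apart by 0.79 (SD 0.35, 0.40 to 1.11 over the 4 pairs). A lower share of smooth muscle cells alone would move them alike. They do not weigh the contractile list itself, so a lower share of these cells stays a candidate cause of its fall. Dye bias and site cannot be told apart for this list: its difference changed between the days by 0.669 on average, with a spread (SD 1.55, -0.89 to 2.70) that covers 0, and every control was Cy3. A lower expression of these genes per cell at the graft may also be the cause and was not tested.

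In the jugular control of replicate 2 at day 14, ADIPOQ stood at 17.75 (8.22 to 9.92 in the other 3 controls of that day), FABP4 at 18.38 (10.48 to 12.28), LPL at 15.10 (7.39 to 10.07) and MYH11 at 13.67 (16.80 to 17.41). An exchange of its label with the anastomosis sample of its array was argued against: 65.5% of the 2336 genes that passed with a 2-fold change at day 5 kept their direction in this pair, where an exchange would turn most of them (92.2%, 90.4% and 97.7% in replicates 1, 3 and 4, and for the downstream pairs of replicates 1 to 4 it was 50.1%, 56.6%, 95.4% and 77.8%), and SCARA5 stood at 15.26 in it and 11.30 at that anastomosis (14.31 to 15.33 in the other 3 controls), SPP1 at 10.69 and 13.79 (8.33 to 9.23) and THBS4 at 10.53 and 16.50 (8.30 to 8.92). Adipose tissue in the sample is a candidate explanation: 21 of 22 measured adipocyte markers, of which 1 stood in another list too and 18 were well above background in each of the other 3 controls, exceeded each of those controls, beside 17 of 18 contractile genes below them. Neutrophil (9 of 11 above, median 1.95), T and NK cell (14 of 18, 1.38), interferon (21 of 25, 1.20) and blood cell genes (9 of 10, 1.65) were higher in it too and fibrillar collagen (14 of 25 below, -1.17), TGF-beta (14 of 24, -1.20) and cell cycle genes (15 of 27, -0.59) lower; their source was not tested, and a wrong label other than this exchange, or a sample from elsewhere, stays open. This was not the sole library with much ADIPOQ at day 14: it stood at 16.42 at the anastomosis of replicate 3 and at 16.77 and 15.77 in the downstream veins of replicates 2 and 4, where adipose tissue was not tested.

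Single pairs stood far from the other 3 in 8 of 146 gene differences and 4 of 57 list medians tested, where chance gives about 1 in 20. At the anastomosis against the control at day 14, THBS4 was 8.18 in replicate 3 (others 5.97 to 6.21), and in replicate 2 TP23 was -5.10 (-4.20 to -4.08), MYOC -6.75 (-2.30 to -1.80) and PDLIM3 -0.048 (-3.61 to -3.39). At day 5 SOX18 was 0.61 at the anastomosis of replicate 2 (1.36 to 1.44). Downstream at day 5, replicate 1 differed in SPARCL1 (-0.80, others -3.86 to -3.37), CDK1 (1.22, others 2.60 to 2.79), TOP2A (0.92, others 2.39 to 2.49) and the cell cycle median (0.32, others 1.54 to 1.71). The cell cycle median of the anastomosis against the downstream vein at day 5 was 2.26 in replicate 1 (0.23 to 0.53), and in replicate 2 the fibrillar collagen median of that contrast at day 14 was 2.07 (-0.17 to 0.03) and the contractile change between days downstream 2.98 (-0.22 to 0.24).

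Differences from the control that themselves changed from day 5 to day 14, by the interaction test of the list, were at the anastomosis cell cycle (-1.68), folding (-0.29), complement (0.48), fibrillar collagen (0.56), adipocyte (0.73), macrophage (0.27), cytokine (-0.63), contractile (0.62), neutrophil (-0.21) and hypoxia genes (-0.22). Downstream they were cell cycle (-1.42), contractile (0.75), macrophage (-0.47) and folding genes (-0.32). Between the graft sites they were macrophage (0.83), fibrillar collagen (0.61), complement (0.32), cell cycle (-0.26) and protease genes (0.24). With an estimated correlation 0 of these were called, and 0 with fry. Without each of replicates 1 to 4 in turn the cell cycle change at the anastomosis alone kept its call and a median within 1.5 times the value given.

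On the arrays of the downstream samples, the green channel, which no label names, correlated best with the jugular control of the same number and day in 8 of 8 cases, at 0.996 or more across probes, against at most 0.992 with any other control and 0.991 with the red channel of its own array.

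For the pairs of sites, 8 splits of the samples exchange the members of whole pairs, too few for a share under 0.05. Fitted on the samples compared with a block, the real split called 9265 and 58 features at the anastomosis at days 5 and 14. It called 3289 and 0 downstream and 0 and 0 between the graft sites, and the highest other called 0 in each. Thus 1, 1, 1, 8, 8 and 8 splits called as many. The change between days at the anastomosis relative to the control was fitted on the 8 differences within pairs. There 1 of 35 splits, the real one, called 67 features and the highest other 0. That is the smallest share that 35 splits can give, 12 comparisons were split, and the fit on all samples called 0 features. Chance was therefore not excluded for this count. Where the real split called 0, every split called as many by construction (35 of 35), so the splits cannot speak to chance. This held for the change between days downstream and between the graft sites (highest other 387 and 0). It also held for day 14 against day 5 in the control and downstream (highest other 4232 and 4451). At the anastomosis 2 of 35 splits called as many as the real 2, and the other, with 3354, was the split of replicates 1 and 2 against 3 and 4, so that this share rests on that batch; with a replicate block, and within replicates 1 and 2 and replicates 3 and 4, limma called 0 (4935, 4758 and 2156 at an unadjusted p under 0.05). These 3 maxima between days came from the same split, which follows the protocol version and points to a structure of the samples. Without a block, that split called 4697, 3104, 5363, 3896, 7002 and 3604 features in the 6 comparisons of sites. The real split called 3171, 91, 0, 0, 0 and 0, so 2, 2, 35, 35, 35 and 35 of 35 splits called as many.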

How the results depend on the processing

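The value table without its replicate 4 columns, replicates 1 and 2 only and replicates 3 and 4 only were chosen after seeing the data. Among the genes named here, 2996 of 3552 values under an alternative kept their side of the threshold, and the called ones among them their direction. Of the rest, 506 lost and 50 gained a call, and 0 called values turned. Turns of values that were not called were not counted. Among the gene lists called in the text, 1083 of 1376 kept direction and call, 286 lost the call and 7 turned. Fewer probes were well above background in replicates 1 and 2; how far this limits weak genes was not tested. Counts below are features past the threshold in limma. Unless named otherwise, they are for the anastomosis and then the downstream vein against the control, at days 5 and 14 each. Where fewer samples are not the cause by construction, the cause was not tested.

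They were 6445, 2936, 2722 and 305 in the text and became 10956, 13703, 8647 and 10069 with median centring and 12735, 6046, 12674 and 63 with sample weights, which also called 26 between the graft sites at day 5. With no replicate block they were 2285, 575, 324 and 11, and the pairing did not change the count of 0 in the other comparisons of sites. The slide as a block gave 6445, 2949, 2721 and 320. Slides and blocks were the same except in replicate 4, so this is nearly the fit in the text. With replicates 1 and 2 only they were 2, 1, 0 and 0 (2494 and 2631 unadjusted downstream). With replicates 3 and 4 only they were 3959, 3227, 3353 and 1796. With only the samples compared they were 9288, 57, 3305 and 0 (3440 unadjusted). The value table gave 8545, 3735, 6605 and 590, and without its replicate 4 columns 4487, 640, 1242 and 13; its share of higher calls downstream at day 14 was 51.0%, and without those columns the share at the anastomosis at day 14 was 66.7%. No background correction gave 478 downstream at day 14. Over the replicates left out in turn the counts ran from 2393 to 5131, 139 to 3048, 2 to 4415 and 4 to 350.

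Between the graft sites, processed signals called 1 feature and the value table without its replicate 4 columns 1 at day 5, where leaving out a replicate gave 0 to 1; at day 14 loess alone called 106, the value table called 8, or 1 without its replicate 4 columns, and leaving out a replicate 0 to 440. For the change between days at the anastomosis relative to the control, the counts were 1 with processed signals, 66 with only the samples compared, 46 with the value table, 1 without its replicate 4 columns and 0 to 1 without a replicate; relative to the downstream vein the value table gave 9. For day 14 against day 5 at the anastomosis, the 2 calls became 1 with no background correction, single-channel quantiles, median centring or the stricter filter, 0 with loess alone (1991 unadjusted), 0 with a replicate block (4935 unadjusted), 0 with replicates 1 and 2 only (4758 unadjusted) and with replicates 3 and 4 only (2156 unadjusted), 0 without any 1 replicate, 16 with only the samples compared, 3029 with the value table and 56 without its replicate 4 columns. In the control the value table gave 21, or 2 without those columns, and only the samples compared 2; downstream these were 52, 2 and 2, with 1 for processed signals and 1 for eBayes with trend and robust. A pairing of day 5 with day 14 by number rests on the number alone (deviations correlated at 0.0732 to 0.622, 11 of 12 over 0.1), and the replicate block called 0 in the control and downstream as well. The slide as a block and within-array log ratios were not run between days within a site.

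Of gene list tests, 86 were called in the text, 74 to 101 under other processing or without a replicate, 24 with fry and 0 with an estimated correlation. The mitochondrial list downstream at day 5 turned to 0.44 with median centring. Over the replicates left out, medians ran from 0.12 to 0.65 for fibrillar collagen between the graft sites at day 14 and from -0.49 to 0.20 for its change between days downstream, from -0.15 to 2.03 for the adipocyte and -0.049 to 1.08 for the contractile change between days at the anastomosis relative to the control, and from -0.12 to 0.47 for interferon and -0.33 to 0.96 for adipocyte genes between days in the control.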

Other observations

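No tests were added for the levels given here, and these genes were picked after their values were seen. Along the vein, the ferritin receptor SCARA5 stood lowest at the anastomosis, at 9.39 ± 0.58, 12.14 ± 1.24 downstream and 15.23 ± 0.49 in the control at day 5, and at 11.34 ± 0.49, 13.55 ± 0.81 and 15.01 ± 0.48 at day 14 (log2 intensity ± SD, n = 4). THBS4 stood at 13.14 ± 0.71 at the anastomosis and 13.46 ± 1.74 downstream at day 5 and at 15.73 ± 1.28 and 14.40 ± 1.84 at day 14, with controls at 10.003 ± 1.42 and 9.13 ± 0.97. For TP23, which was lower than in the control at both graft sites at day 14, the control itself stood at 9.90 ± 1.68 at day 5 and 14.04 ± 0.82 at day 14, beside 7.69 ± 0.79 and 9.66 ± 0.93 at the anastomosis. The complement inhibitor C4BPA stood at 16.60 ± 0.27 and 15.31 ± 0.32 in the control and at 14.19 ± 0.59 and 15.81 ± 0.40 at the anastomosis at days 5 and 14.

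The heat shock genes that fell at the graft sites at day 14 differed widely between controls. HSP70.2 stood at 18.05, 17.36, 11.61 and 13.81 in the controls of replicates 1 to 4 at day 5 and at 15.57, 17.23, 11.82 and 17.44 at day 14, and HSPA6 at 14.79, 12.16, 8.51 and 10.81 and 11.66, 16.09, 8.38 and 14.19. At the anastomosis at day 14 HSP70.2 stood at 12.87, 14.46, 10.36 and 13.51 and HSPA6 at 9.93, 11.02, 7.45 and 8.76. MYOC stood at 8.63, 16.60, 10.87 and 9.24 in the day 14 controls of replicates 1 to 4 and at 7.48, 14.07, 8.48 and 10.87 in the downstream veins of that day.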
